A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

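The samples were 12 hybridisations of budding yeast RNA to two-channel spotted arrays. Channel 1 held RNA of a deletion mutant, FY31 (snf2) or YPS1 (swi1), and channel 2 RNA of the wild type FY2, from minimal medium or from the rich medium YPD, with 3 arrays for each of the 4 groups. The labels do not say whether arrays of a group came from separate cultures, so p-values measure only the spread between these arrays.

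The authors deposited 1 value per probe and array, in 3 tables, 1 per array platform. The deposited values are log2 ratios of the 2 channels, read from images with ScanAlyze, per the labels; whether arrays were normalised, which channel is the numerator and how the values were centred or scaled stay unknown. Base 2 was settled for the table of 8 arrays from the values. On these arrays 13.3% to 17.3% of values equalled, to 3 decimals, the log2 of a ratio of 2 whole numbers up to 20, against 6.14% to 6.61% on a shifted lattice, and 73 to 145 values were exactly 0 where neighbouring values held 2.25 to 6.30 on average. This also shows that many spots were very dim. No such excess was seen in the 2 tables of replicate 1, for which base 2 was only taken over. Signal over background is not given in the sources used here.

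The medians of the deposited columns were, for replicates 1, 2 and 3, -0.08, -0.05 and -0.08 in snf2 minimal, -0.13, -0.08 and -0.03 in swi1 minimal, -0.48, -0.11 and -0.13 in snf2 rich, and -0.07, -0.09 and -0.13 in swi1 rich. Missing values made up 5.92%, 7.25% and 11.3% of probes in snf2 minimal, 6.47%, 8.80% and 10.3% in swi1 minimal, 16.1%, 14.2% and 40.0% in snf2 rich, and 3.19%, 11.4% and 16.2% in swi1 rich. Centring each array on its median over genes shifted values by over 0.1 on 3 of the 8 arrays, by 0.11 on both snf2 rich arrays and by 0.10 on swi1 rich replicate 3, so changes are relative to the median gene of an array.

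The labels name no dyes, so the direction of the ratios is not stated. The rule set in advance read it from the deleted genes. SNF2 alone, read by that rule, would give a positive deposited value as higher in the mutant, and the SWI1 probes differed in sign, so the rule did not settle it. The direction used was chosen after seeing the data and departs from that rule, which would otherwise have left sizes and counts only. The deposited ratio was taken as wild type over mutant and every value was turned to mutant over wild type. This is called likely because the wild type is channel 2 and is named first in the labels, and because ScanAlyze's ratio is channel 2 over channel 1. The known dependence of single genes on Snf/Swi is mixed and decides little. That all arrays run 1 way is an assumption. They correlate positively, which holds under either reading and which a bias of single genes shared by all arrays would also give. With the opposite reading every higher becomes lower. Marker genes did not settle it either. No array of a known other dye orientation is among those used, so a dye bias of single genes is not separable in tests against 0. It cancels in differences between groups only if it is the same on all arrays. The wild-type RNA is the other channel of every array. Whether it was shared between arrays is not given, so how far its own spread enters is unknown.

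Probes were named from the platform's gene table. In the table of 8 arrays 6956 of 8832 probes had 1 gene (5574 genes, 1259 of them with more than 1 probe) and 1876 were unnamed, and the tables of replicate 1 had 5548 of 6400 and 5516 of 6384 probes named. Gene symbols were matched to the locus tags of the reference annotation, which gave names, gene order and the start and end positions used to leave out overlapping neighbours. Spots of a gene were averaged; before averaging, the 2 spots of a gene correlated at r = 0.54 to 0.67 across genes on an array. Of unnamed probes tested alone, limma called 124 of 1141 in snf2 minimal, 117 of 1112 in swi1 minimal, 170 of 680 in snf2 rich and 245 of 943 in swi1 rich.

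limma 3.58.1 (R 4.3.3) was fitted to the 8 arrays with 1 mean per group, separately for each of 8 comparisons, on genes measured on both arrays of each group involved. Each mutant and medium was tested against 0, the 2 mutants against each other within a medium, and minimal against rich medium within a mutant, two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Errors are limma's moderated standard errors, n = 2 arrays per group. Replicate 1 entered no test of the main comparisons and was used for the share of called genes with the same sign. The replicate numbers were not taken to pair the samples. Correlations and shared calls between groups are across genes, and covariances were set beside those of simulated arrays without effects that share wild-type RNA between arrays of 1 replicate number.

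Before the data were examined, 30 gene lists, the tests, the alternatives and the rule for named genes were fixed. They covered Snf/Swi and other remodeller subunits, reported targets, phosphate, phospholipid, sugar, respiratory, amino acid, sulfur, nitrogen, nucleotide, vitamin, metal and sterol metabolism, histones, mating, cell cycle, cell surface, ribosome, stress, meiosis, chromosome-end, Ty and marker genes. The Ty list matched no gene name, which left 29. Lists with at least 4 measured members were tested with limma's cameraPR on the moderated statistics at a preset inter-gene correlation of 0.01, adjusted over 115 list and group pairs, which gave 42 calls. With a correlation estimated from the arrays, 0 of 112 passed and the smallest adjusted p was 0.132. That test took in only members measured on all 8 arrays, such as 6 nitrogen genes, 5 histones and 7 M/G1 genes. At the preset correlation 33 passed on these genes, 11 of the 42 calls being lost and 2 gained, so the members used account for part of the losses. Members and correlation are not all that differs. For COS and Y' helicase genes in snf2 rich both tests took 14 members, and the estimated correlation was 0.00932. Unadjusted p was still 1.74e-06 with cameraPR and 0.00907 in the test with an estimated correlation. The test with an estimated correlation also rests on the 4 residual degrees of freedom of the fit. The cameraPR test at a preset correlation does not. With so few, the former has little power. Failing it is therefore not put down to members or correlation alone, and does not show that correlation between genes undoes a call. G2/M genes, uncalled, turned from down to up in the 4 groups between the 2 tests. limma's fry, which asks whether the genes of a list move on balance 1 way and compares them with no other genes, passed 75, 38 of them among the 42. Members were counted over all genes tested and adjusted over the list alone.

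Named genes were SNF2 and SWI1, the 8 highest and 8 lowest called genes per group with a standard symbol and the same sign on all arrays, up to 3 members per list and group with the largest change among those called (up to 2 where none was), the 4 highest and lowest called genes per difference (3 with the smallest p where none passed), and all members of the lists of subunits, reported targets, histones and markers. Not all are printed, and genes outside this rule are said to be chosen after their values were seen.

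The pipeline was tested on simulated data with 100 genes set to each of 2 sizes. Of genes set at a log2 of 1, 83.4% to 87.6% were recovered in the 4 groups and 70.2% and 75.0% in the medium differences, and 3.92% to 5.84% of calls were false. The simulated noise was normal and independent between arrays, without shared wild-type RNA, dye bias or errors of dim spots. These shares therefore check the code and do not give the false share in the real data. Alternatives were no centring, scaling to 1 spread, genes measured on all 8 arrays, a robust variance model, a replicate block, all 12 arrays with and without platform as a random block, only the arrays compared, a 2-fold requirement, a rule of 2-fold on both arrays without a test, and each array left out in turn. With an array left out, its group was tested on all genes measured on the array left, which were more than in the main fit. Values at small whole-number ratios left out, genes with a single probe, and the list test on medium differences were added after seeing the data. Other tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, statmod 1.5.0 and matplotlib 3.10.9.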

Results

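Expression was measured on 12 two-channel spotted arrays of budding yeast RNA, each setting RNA of 1 deletion mutant against RNA of the wild-type strain FY2. The mutants lacked SNF2 (strain FY31), which encodes the ATPase of the Snf/Swi chromatin-remodelling complex, or SWI1 (strain YPS1), which encodes another subunit of that complex. Both were grown in minimal medium and in the rich medium YPD, which made 4 groups of 3 arrays. The comparisons ask which genes change when either subunit is missing, whether the 2 mutants act alike, and whether the effects depend on the medium. Replicates 2 and 3 of every group shared 1 array platform and entered the tests (8 arrays, n = 2 per group), and replicate 1 of each group, on other platforms, was set beside them. Between 5299 and 8192 of the 8832 probes were measured on these 8 arrays, with the lowest number on snf2 rich replicate 3. The number of arrays limits the precision.

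Signs give mutant over wild type, a direction that is likely but not stated by the labels. It turns the deposited sign, so with the opposite reading every gene described as higher would be lower and the reverse. The deleted genes did not settle it. The deposited SNF2 values on arrays labelled snf2 were -0.85 and -1.07 in minimal medium (replicates 2 and 3) and -0.79 and -0.76 in rich medium. Under the direction used, SNF2 (YOR290C) therefore read higher on arrays labelled snf2, by 0.89 ± 0.15, adjusted p = 0.00467 in minimal medium and by 0.67 ± 0.15, adjusted p = 0.0104 in rich medium. Without snf2 minimal replicate 3 the former did not pass (adjusted p = 0.0722), and without snf2 rich replicate 2 or 3 the latter did not (adjusted p = 0.0741 and 0.0745). On arrays labelled swi1, 1 SWI1 probe had deposited values of 0.75 and 0.44 in minimal medium and 1.26 on rich replicate 2, which is lower in the mutant. Another SWI1 probe had deposited values of -1.32 and -0.68 on the rich replicates, which is the opposite. On arrays of the other mutant this probe had 0.68 and 1.29 (snf2 minimal replicates 2 and 3). The first SWI1 probe had -0.52 on snf2 minimal replicate 2 and -0.415 on snf2 rich replicate 3. SNF2 was near 0 on both swi1 minimal replicates (0.029 and -0.029) and on swi1 rich replicate 2 (0.003), but 0.62 on swi1 rich replicate 3. On replicate 1, SNF2 read 0.43 in snf2 minimal and -0.68 in snf2 rich, and SWI1 read 1.36 in swi1 minimal and -0.50 in swi1 rich (centred, mutant over wild type, signs on the assumption that these arrays run the same way). Which part of each gene was deleted, and what the probes cover, is not given in the sources used here, so these probes may check nothing. The basis for the direction used is that the labels put wild type in channel 2 and name it first. All 66 pairs of the 12 arrays correlated positively across genes (r from 0.19 to 0.86) under either reading. That the arrays run 1 way is taken over and not settled by this, since a bias of single genes shared by all arrays would also give positive r. Background knowledge of single genes is mixed. In the list of genes with reported Snf/Swi-dependent transcription, 0 and 0 were called higher and 6 and 5 lower in minimal medium (snf2, swi1). In rich medium 2 and 1 were called higher and 1 and 3 lower, and the list test called no group. Snf/Swi is known to repress SER3 and to be needed for PHO84 transcription, and both genes match the direction used. INO1, HO and SUC2 are also known to need Snf/Swi. INO1 stood at -1.08 in snf2 minimal, a call lost without snf2 minimal replicate 2 (adjusted p = 0.354), while HO at 0.75 in snf2 rich and SUC2 at 0.58 and 0.78 in snf2 and swi1 rich run against it (SUC2 in snf2 rich did not pass without replicate 2, adjusted p = 0.0552).

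On arrays labelled snf2 in minimal medium, ZEO1 (YOL109W), a plasma membrane protein tied to cell integrity signalling, changed by -4.95 ± 0.13, adjusted p = 3.92e-06 on the log2 scale. SAG1 (YJR004C), the alpha-agglutinin of mating, changed by -4.76 ± 0.12, adjusted p = 3.58e-06, and QDR2 (YIL121W), a plasma membrane transporter, by -4.39 ± 0.11. DAL5 (YJR152W), the allantoate permease, changed by -4.43 ± 0.31, and HSP12 (YFL014W), a stress-induced membrane protein, by -4.10 ± 0.23. MF(ALPHA)2, a gene for alpha-factor, changed by -4.10 ± 0.12. The asparaginase gene ASP3-1 changed by -4.08 ± 0.10, but its near-identical copies cannot be separated by a probe. BNA2 (YJR078W), a tryptophan dioxygenase of NAD synthesis, rose by 2.10 ± 0.16, adjusted p = 0.000128. RTS3 (YGR161C), linked to protein phosphatase 2A, rose by 1.91 ± 0.23. SER3 (YER081W), the phosphoglycerate dehydrogenase of serine synthesis, rose by 1.52 ± 0.12, adjusted p = 0.000152. EMI2 (YDR516C), a hexokinase relative, rose by 1.61 ± 0.14, and THI11 of thiamine precursor synthesis, which has near-identical copies, by 1.63 ± 0.10.

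limma called 1550 of 5307 genes for snf2 in minimal medium, 678 higher and 872 lower, of which 251 changed at least 2-fold (55 higher and 196 lower). Without centring of the arrays 920 were higher and 769 lower, so the balance of the counts rests on centring. The count was 770 without snf2 minimal replicate 2 and 685 without replicate 3. Of the called genes measured on replicate 1, 82.6% (1188 of 1438) had the same sign there, against 66.8% of all genes, and 198 of 222 of those called at 2-fold or more did.

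On arrays labelled swi1 in minimal medium, ZEO1 changed by -4.95 ± 0.14, adjusted p = 5.44e-06, DAL5 by -4.49 ± 0.31, HSP12 by -4.44 ± 0.23 and QDR2 by -4.36 ± 0.11. SAG1 changed by -4.20 ± 0.12, and YRO2 (YBR054W), a plasma membrane protein of the opsin-like family, by -4.16 ± 0.18. BNA2 rose by 2.37 ± 0.16, adjusted p = 8.16e-05 and THI11 by 1.93 ± 0.10. COS12 (YGL263W), a member of a repeated family near chromosome ends, rose by 1.82 ± 0.09. MMP1 (YLL061W), an S-methylmethionine permease, rose by 1.69 ± 0.10, and MAL31 (YBR298C), a maltose permease, by 1.55 ± 0.10. For swi1 in minimal medium limma called 1526 of 5354 genes, 736 higher and 790 lower (908 and 684 without centring). Of these 272 changed at least 2-fold, 64 up and 208 down. The count was 586 without swi1 minimal replicate 2 and 703 without replicate 3. On replicate 1, 80.5% of 1407 called genes had the same sign against 65.4% of all genes, and 231 of 246 of those called at 2-fold or more.

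**Figure D1:**
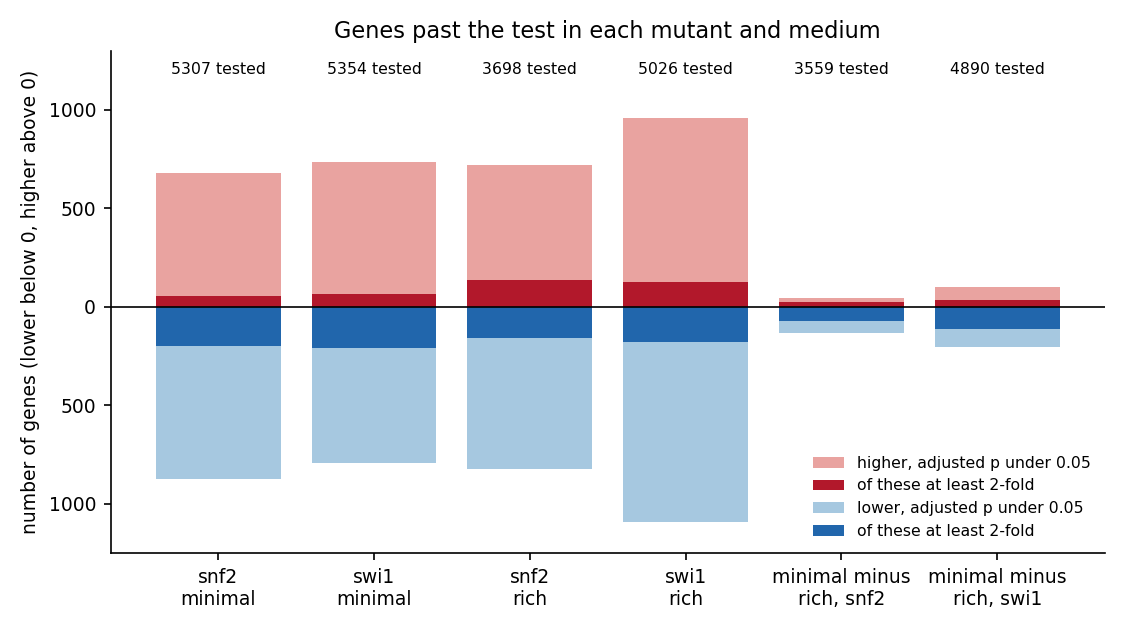
Bars give the number of genes that limma called higher (up) or lower (down) at an adjusted p under 0.05 for the 4 mutant groups and the 2 differences between media, with the darker part at 2-fold or more. The mutant groups had 1526 to 2051 called genes and the differences between media 178 and 306.

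Groups of genes fell together in both mutants in minimal medium. Values of groups are in the order snf2, swi1, and adjusted p is at the preset correlation unless stated. The test with an estimated correlation took in only members measured on all 8 arrays. It rested on 4 residual degrees of freedom and had little power, so its failures alone do not decide. For cytoplasmic ribosomal proteins, 117 and 99 of 132 fell and 0 rose (121 and 112 lower and 0 higher adjusted over the list alone). This gave adjusted p = 9.91e-21 and 2.45e-15, and adjusted p = 0.132 and 0.138 with an estimated correlation. RPL42B (YHR141C) stood at -1.15 ± 0.13 and -1.11 ± 0.13, and RPS30A (YLR287C-A) at -1.34 ± 0.11 and -1.05 ± 0.11. For ribosome biogenesis and RNA polymerase I, 30 and 26 of 38 and 37 fell and 0 rose (32 and 30 lower and 0 higher adjusted over the list alone). The group had adjusted p = 1.18e-07 and 7.78e-06, and adjusted p = 0.141 and 0.141 with an estimated correlation. NOP7 (YGR103W), a factor of the large ribosomal subunit, stood at -1.07 and -0.91.

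Among mating-type specific and pheromone response genes, 16 and 15 of 22 fell and 0 and 2 rose (16 and 16 lower and 1 and 2 higher adjusted over the list alone). They had adjusted p = 2.61e-29 and 2.90e-23, and adjusted p = 0.132 and 0.132 with an estimated correlation, with medians of -1.38 and -1.24. AGA1 (YNR044W), the anchor of a-agglutinin, stood at -3.46 ± 0.15 and -3.47 ± 0.15. Among M/G1 and daughter-cell genes, 11 and 12 of 15 and 16 fell and 0 rose (11 and 12 lower and 0 and 1 higher adjusted over the list alone). The list had adjusted p = 5.48e-10 and 8.67e-11, and adjusted p = 0.141 and 0.141 with an estimated correlation. DSE1 (YER124C), a daughter-cell gene, stood at -2.43 ± 0.14 and -2.51 ± 0.14. SCW11 (YGL028C), a cell wall glucanase of cell separation, stood at -1.97 ± 0.19 and -2.33 ± 0.19. Among core histone genes, 7 and 8 of 10 fell and 0 rose (7 and 8 lower and 0 and 1 higher adjusted over the list alone). Histones had adjusted p = 0.0098 and 0.00242, and adjusted p = 0.307 and 0.29 with an estimated correlation. On the 5 histone genes measured on all 8 arrays neither passed (adjusted p = 0.072 and 0.0626). HTA2 (YBL003C), a histone H2A gene, stood at -0.94 ± 0.10 and -1.17 ± 0.10.

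Among glycolysis and ethanol fermentation genes in minimal medium, 12 and 10 of 20 and 18 fell and 2 and 3 rose (13 and 12 lower and 3 and 4 higher adjusted over the list alone). That list had adjusted p = 1.07e-05 and 6.27e-05, and adjusted p = 0.317 and 0.335 with an estimated correlation. The glyceraldehyde-3-phosphate dehydrogenase genes TDH1 (YJL052W) and TDH2 (YJR009C) stood at -1.66 and -1.75 and at -1.53 and -1.68. Of nitrogen catabolite repressed genes, 12 and 13 of 21 and 20 fell and 2 and 2 rose (15 and 13 lower and 3 and 2 higher adjusted over the list alone). Nitrogen genes had adjusted p = 7.02e-12 and 7.12e-13, and adjusted p = 0.615 and 0.529 with an estimated correlation, with medians of -1.28 and -1.23. Both calls were lost on the 6 nitrogen genes measured on all 8 arrays (adjusted p = 0.72 and 0.561). Besides DAL5, PUT1 (YLR142W), proline oxidase, changed by -3.01 ± 0.30 in snf2 and -3.21 ± 0.30 in swi1. Of genes for arginine, histidine, lysine and branched-chain amino acids, 19 and 15 of 33 and 31 fell and 3 and 2 rose (21 and 17 lower and 3 and 2 higher adjusted over the list alone). Amino acid genes had adjusted p = 0.00513 and 0.0114, and adjusted p = 0.341 and 0.341 with an estimated correlation. Both calls were lost on genes measured on all 8 arrays (adjusted p = 0.0627 and 0.0574) and with all 12 arrays and platform as a random block (adjusted p = 0.133 and 0.379). HIS4 (YCL030C) of histidine synthesis stood at -1.57 and -1.56 and LYS9 (YNR050C) of lysine synthesis at -1.37 and -1.48. The COS and Y' helicase genes near chromosome ends went the other way: 13 and 13 of 19 rose and 0 fell (16 and 13 higher and 1 and 2 lower adjusted over the list alone). Their list had adjusted p = 2.74e-06 and 1.88e-07, and adjusted p = 0.132 and 0.132 with an estimated correlation. These repeated genes share sequence, so their probes are not separate measurements.

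In the phosphate regulon, 6 and 4 of 14 and 15 fell and 1 and 1 rose (6 and 7 lower and 1 and 1 higher adjusted over the list alone) in minimal medium. It had adjusted p = 0.0443 and 0.117, and adjusted p = 0.614 and 0.67 with an estimated correlation. The snf2 call was lost without snf2 minimal replicate 2 or 3 (adjusted p = 0.0915 and 0.0618), and on genes measured on all 8 arrays (adjusted p = 0.64). PHM8 (YER037W), a phosphatase, stood at -2.10 and -2.38. In ergosterol biosynthesis, 7 and 8 of 23 rose and 3 and 2 fell (9 and 12 higher and 3 and 2 lower adjusted over the list alone). Sterol genes had adjusted p = 0.188 and 0.0297, and adjusted p = 0.303 and 0.256 with an estimated correlation, and the swi1 call was lost without swi1 minimal replicate 2 (adjusted p = 0.0501) and on genes measured on all 8 arrays (adjusted p = 0.0702). MVD1 (YNR043W) of the mevalonate pathway stood at 0.87 and ERG5 (YMR015C), the sterol desaturase, at -0.83 in swi1.

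On arrays labelled snf2 in rich medium, YHB1 (YGR234W), the nitric oxide detoxifying flavohemoglobin, changed by -4.06 ± 0.09, adjusted p = 4.20e-07. PHO84 (YML123C), the high-affinity phosphate transporter, changed by -3.80 ± 0.13, adjusted p = 3.51e-06. YRO2 changed by -3.88 ± 0.18, ZEO1 by -3.39 ± 0.14 and SAG1 by -3.19 ± 0.12. ATF2 (YGR177C), an alcohol acetyltransferase, changed by -3.58 ± 0.15, and TAT1 (YBR069C), an amino acid permease, by -3.95 ± 0.54. SER3 rose by 3.79 ± 0.12, adjusted p = 3.16e-06. MET17 (YLR303W), the O-acetylhomoserine sulfhydrylase of methionine synthesis, rose by 3.79 ± 0.09, adjusted p = 4.20e-07. RTS3 rose by 3.26 ± 0.23, and MET3 (YJR010W), ATP sulfurylase, by 2.98 ± 0.13. On replicates 2 and 3 TAT1 read -2.48 and -5.43, so its size rests on the array. The same holds for AAC1 (YMR056C), a mitochondrial ADP/ATP carrier (4.14 ± 0.58, with 2.58 and 5.70 on the 2 arrays), and CAR1 (YPL111W), arginase (3.97 ± 0.70, with 2.14 and 5.79).

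For snf2 in rich medium limma called 1543 of 3698 genes, 721 higher and 822 lower (998 and 630 without centring). Of these 291 changed at least 2-fold, 135 up and 156 down. Fewer genes could be tested because replicate 3 lacked 40.0% of its values. The count was 1029 without snf2 rich replicate 2 and 1197 without replicate 3. On replicate 1, 64.7% of 1296 called genes had the same sign against 57.1% of all genes, and 197 of 248 of those called at 2-fold or more. The deposited values of that array had a standard deviation of 1.40, against 0.60 to 0.83 on the other 11.

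On arrays labelled swi1 in rich medium, YHB1 changed by -3.95 ± 0.09, adjusted p = 8.79e-07, ZEO1 by -3.62 ± 0.13 and SAG1 by -3.61 ± 0.12. MRH1 (YDR033W), a plasma membrane protein related to YRO2, changed by -3.23 ± 0.11. PHO84 changed by -3.12 ± 0.13, adjusted p = 1.61e-05, and YGP1 (YNL160W), a secreted cell wall glycoprotein, by -2.91 ± 0.10. MET17 rose by 3.77 ± 0.08, adjusted p = 8.79e-07 and MET3 by 2.86 ± 0.13. LEU2 (YCL018W) of leucine synthesis, which is also a common strain marker, rose by 2.69 ± 0.18. CIT2 (YCR005C), the peroxisomal citrate synthase, rose by 2.62 ± 0.37, and MET6 (YER091C), methionine synthase, by 2.61 ± 0.14. For swi1 in rich medium limma called 2051 of 5026 genes, 958 higher and 1093 lower (1226 and 866 without centring). Of these 305 changed at least 2-fold, 125 up and 180 down. The count was 1054 without swi1 rich replicate 3 and 1416 without replicate 2. On replicate 1, 73.3% of 1978 called genes had the same sign against 62.0% of all genes, and 240 of 292 of those called at 2-fold or more.

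**Figure D2:**
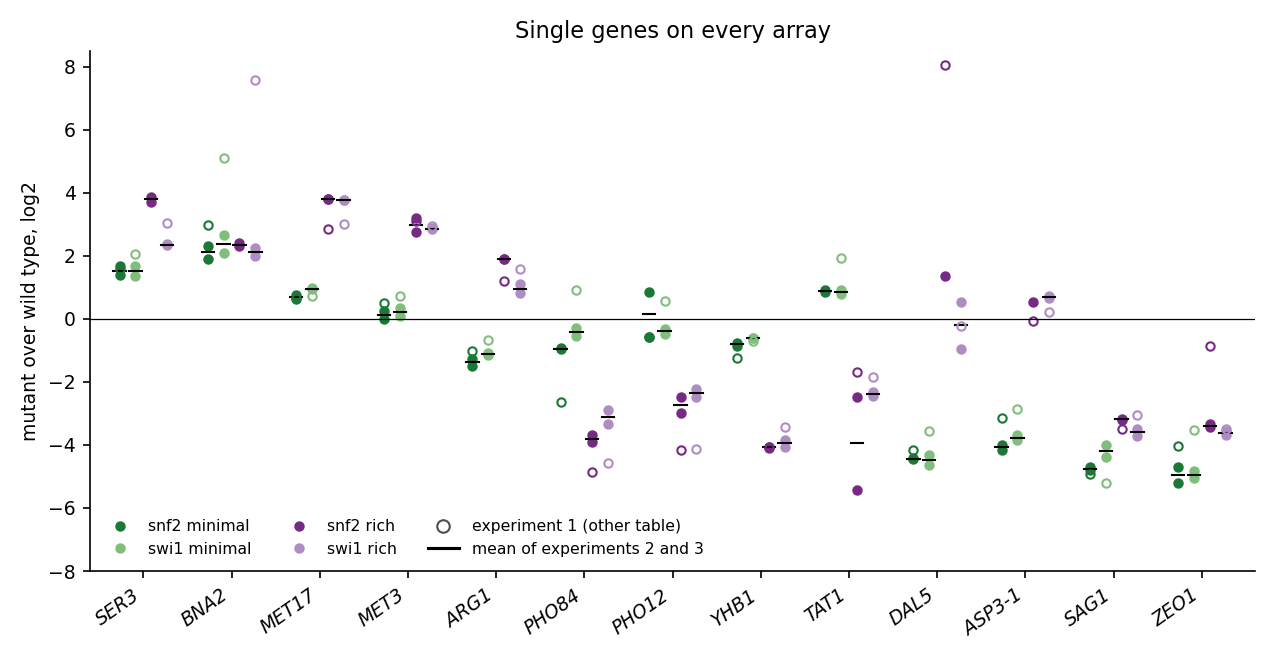
Points give the log2 ratio, mutant over wild type, on each array for 13 genes in the 4 groups; filled points are replicates 2 and 3, open points replicate 1 on other platforms, and ticks the mean where replicates 2 and 3 were both measured. ZEO1 and SAG1 were low and BNA2 and SER3 high in all 4 groups, while MET17, MET3, PHO84 and YHB1 moved further from 0 in rich medium.

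In rich medium, methionine and sulfate assimilation genes went up: 13 and 16 of 18 and 22 rose and 1 and 1 fell (13 and 16 higher and 1 and 1 lower adjusted over the list alone), in the order snf2, swi1. Sulfur genes had adjusted p = 2.83e-17 and 2.84e-22, and adjusted p = 0.141 and 0.149 with an estimated correlation, with medians of 1.61 and 1.27. MET13 (YGL125W), a methylenetetrahydrofolate reductase, stood at 2.73 and 2.42. In minimal medium, 4 and 3 of 23 and 20 rose and 4 and 4 fell (4 and 3 higher and 4 and 4 lower adjusted over the list alone). The list was not called there (adjusted p = 0.85 and 0.775). SUL1 (YBR294W), a sulfate permease, stood at -2.36 and -1.94 and SAM1 (YLR180W), an S-adenosylmethionine synthetase, at -1.23 and -1.06, while MMP1 stood at 1.37 and 1.69. In the phosphate regulon, 9 and 10 of 11 and 13 fell and 0 rose (9 and 10 lower and 0 higher adjusted over the list alone) in rich medium. Phosphate genes had adjusted p = 5.82e-10 and 7.12e-13, and adjusted p = 0.198 and 0.231 with an estimated correlation. The secreted acid phosphatase PHO5 (YBR093C) stood at -2.78 ± 0.12 and -2.51 ± 0.12.

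Of genes for arginine, histidine, lysine and branched-chain amino acids, 14 and 17 of 26 and 30 rose and 7 and 4 fell (14 and 17 higher and 7 and 5 lower adjusted over the list alone) in rich medium. They had adjusted p = 0.00483 and 0.00051, and adjusted p = 0.384 and 0.369 with an estimated correlation. ARG4 (YHR018C) and ARG1 (YOL058W) of arginine synthesis stood at 1.99 and 1.65 and at 1.90 and 0.95, and BAT2 (YJR148W), a branched-chain aminotransferase, at -1.84 in swi1. Of galactose, maltose and sucrose genes, 7 and 6 of 11 and 15 rose and 0 and 2 fell (7 and 6 higher and 0 and 2 lower adjusted over the list alone). Sugar genes had adjusted p = 0.00172 and 0.0244, and adjusted p = 0.141 and 0.141 with an estimated correlation. The swi1 call was lost without swi1 rich replicate 2 (adjusted p = 0.281) and with all 12 arrays and platform as a random block (adjusted p = 0.153). MAL31 stood at 1.30 and 1.32. In minimal medium, 4 and 5 of 12 and 15 rose and 2 and 2 fell (5 and 5 higher and 2 and 2 lower adjusted over the list alone), uncalled at adjusted p = 0.128 and 0.141. On genes measured on all 8 arrays they passed there (adjusted p = 0.0223 and 0.0163). Of nitrogen catabolite repressed genes, 3 and 7 of 6 and 18 rose and 0 and 1 fell (3 and 7 higher and 0 and 1 lower adjusted over the list alone). This list had adjusted p = 0.429 and 0.0299, and adjusted p = 0.602 and 0.453 with an estimated correlation. Without swi1 rich replicate 2 the swi1 call was lost (adjusted p = 0.151), as it was on genes measured on all 8 arrays (adjusted p = 0.398). In snf2, 6 members were measured on both arrays. The list passed without snf2 rich replicate 2 or 3, but those fits took every member measured on the array left. Their members can be more than these 6. GAP1 (YKR039W), the general amino acid permease, stood at 1.93 ± 0.09 in swi1.

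Ribosomal protein genes fell in rich medium as well: 93 and 108 of 103 and 126 fell and 0 rose (94 and 114 lower and 0 and 1 higher adjusted over the list alone). This gave adjusted p = 4.84e-19 and 2.34e-19, and adjusted p = 0.132 and 0.141 with an estimated correlation. In ribosome biogenesis, 24 and 29 of 25 and 36 fell and 0 rose (24 and 31 lower and 0 higher adjusted over the list alone). The group had adjusted p = 6.46e-11 and 2.67e-11, and adjusted p = 0.141 and 0.141 with an estimated correlation. DBP9 (YLR276C), an RNA helicase, stood at -1.37 and -1.25. Among mating genes, 13 and 15 of 17 and 21 fell and 1 and 1 rose (13 and 15 lower and 1 and 1 higher adjusted over the list alone). They had adjusted p = 6.25e-13 and 7.00e-17, and adjusted p = 0.132 and 0.132 with an estimated correlation. Among M/G1 genes, 8 and 10 of 12 and 13 fell and 1 and 0 rose (8 and 10 lower and 1 and 0 higher adjusted over the list alone). The list had adjusted p = 0.0111 and 4.79e-06, and adjusted p = 0.257 and 0.206 with an estimated correlation. ASH1 (YKL185W), a daughter-cell repressor, stood at -1.40 in swi1. Among COS and Y' helicase genes, 12 and 15 of 14 and 19 rose and 0 fell (12 and 15 higher and 0 and 1 lower adjusted over the list alone). Their list had adjusted p = 8.01e-06 and 1.29e-08, and adjusted p = 0.132 and 0.132 with an estimated correlation.

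Among core histones in rich medium, 4 and 7 of 5 and 10 fell and 0 and 1 rose (4 and 8 lower and 0 and 1 higher adjusted over the list alone). Histones had adjusted p = 0.377 and 0.0347, and adjusted p = 0.452 and 0.332 with an estimated correlation. The swi1 call was lost without swi1 rich replicate 2 or 3 (adjusted p = 0.0536 and 0.0841), and on genes measured on all 8 arrays (adjusted p = 0.129). HTA2 stood at -0.94 in swi1. Among heat shock and general stress genes, 11 and 12 of 20 and 29 rose and 1 and 3 fell (13 and 12 higher and 1 and 3 lower adjusted over the list alone). Stress genes had adjusted p = 0.0154 and 0.29, and adjusted p = 0.155 and 0.198 with an estimated correlation. The snf2 call was lost without snf2 rich replicate 3 (adjusted p = 0.106), and with all 12 arrays and platform as a random block the list pointed down (adjusted p = 0.788). TSL1 (YML100W), a trehalose synthase subunit, stood at 2.09 and 0.33, while HSP12 stood at -2.70 in swi1. In minimal medium, 6 and 9 of 30 and 31 rose and 5 and 7 fell (8 and 11 higher and 5 and 7 lower adjusted over the list alone). There the medians were positive (0.24 and 0.19), the means negative (-0.13 and -0.16), and the tests pointed up in snf2 and down in swi1 (adjusted p = 0.842 and 0.92). With all 12 arrays and platform as a random block both pointed down and passed (adjusted p = 0.0452 and 0.0256).

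Among thiamine and pyridoxine genes in snf2 and swi1 in minimal and then in rich medium, 4, 5, 3 and 5 of 17, 16, 12 and 16 rose and 2, 1, 0 and 0 fell (4, 5, 2 and 5 higher and 2, 1, 0 and 0 lower adjusted over the list alone). The test called swi1 in rich medium, with adjusted p = 0.0307 and adjusted p = 0.238 with an estimated correlation. That call was lost without swi1 rich replicate 2 (adjusted p = 0.221) and on genes measured on all 8 arrays (adjusted p = 0.137). In snf2 rich the list passed without replicate 3, in a fit that took every member measured on replicate 2, which can be more than 12. THI13, with near-identical copies, stood at 1.60, 1.56, 1.63 and 1.65, and SNO2 of pyridoxine synthesis at -1.94 in snf2 in minimal medium. Among glycolysis genes, 8 and 8 of 18 fell and 4 and 4 rose (9 and 8 lower and 4 and 5 higher adjusted over the list alone) in rich medium. They were not called (adjusted p = 0.676 and 0.587), but passed with all 12 arrays and platform as a random block (adjusted p = 0.0371 and 0.0208), and GLK1 (YCL040W), glucokinase, stood at 2.22 and 2.11. Among ergosterol genes, 5 and 7 of 17 and 22 rose and 3 and 3 fell (5 and 7 higher and 3 and 3 lower adjusted over the list alone), with adjusted p = 0.869 and 0.605. ERG5 stood at -1.36 in snf2, and in swi1 the median of -0.01 and the mean of 0.05 differed in sign.

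**Figure D3:**
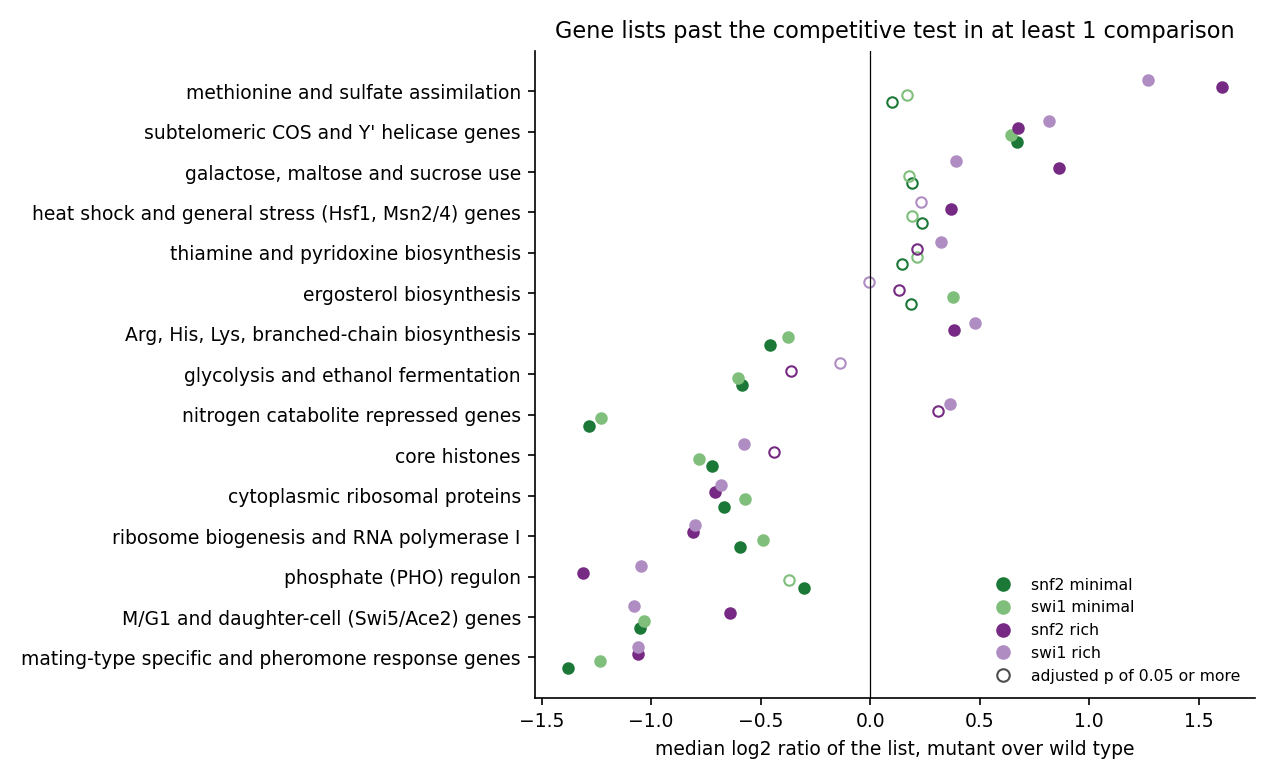
Points give the median log2 ratio, mutant over wild type, of the measured members of 15 gene lists in the 4 groups, filled where the list test at the preset correlation had an adjusted p under 0.05. Ribosomal protein, ribosome biogenesis, mating and M/G1 genes were below 0 in all 4 groups and COS and Y' genes above 0, and methionine genes reached 1.61 and 1.27 in rich medium.

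The other 14 lists tested were called in no group, with a smallest adjusted p of 0.0648. With all 12 arrays and platform as a random block 7 of them passed in 1 to 4 groups, given here as the blocked value. Counts are in the order snf2 minimal, swi1 minimal, snf2 rich, swi1 rich. Of genes for Snf/Swi subunits, 1, 0, 1 and 0 of 12, 12, 7 and 12 rose and 0 fell (1, 0, 1 and 0 higher and 0 lower adjusted over the list alone). The 1 called was SNF2 itself. Of subunits of the other remodellers RSC, ISWI, INO80 and SWR1, 1, 1, 0 and 0 of 21, 22, 15 and 19 rose and 0, 1, 3 and 5 fell (1, 0, 0 and 0 higher and 0, 0, 1 and 5 lower adjusted over the list alone). RSC4 (YKR008W) stood at -0.55 in snf2 rich. Of genes with reported Snf/Swi-dependent transcription, 0, 0, 2 and 1 of 10, 11, 10 and 11 rose and 6, 5, 1 and 3 fell (0, 0, 2 and 1 higher and 6, 5, 1 and 3 lower adjusted over the list alone). ADH1 (YOL086C), the main alcohol dehydrogenase, stood at -1.01 and -1.06 in minimal medium. HO (YDL227C), the mating-type switching endonuclease, stood at 0.75 in snf2 rich, and SUC2 (YIL162W), invertase, at 0.78 in swi1 rich. INO1 of inositol synthesis stood at -1.08 in snf2 minimal (adjusted p = 0.0345), and did not pass without snf2 minimal replicate 2 (adjusted p = 0.354). The list passed in snf2 minimal without replicate 3 (adjusted p = 0.0386). Blocked, it passed in both mutants in minimal medium (adjusted p = 0.00519 and 0.0113). Of phospholipid and inositol genes, 0, 1, 3 and 1 of 13, 13, 8 and 13 rose and 6, 5, 1 and 1 fell (0, 1, 3 and 1 higher and 6, 5, 1 and 1 lower adjusted over the list alone). CHO2 (YGR157W), a phosphatidylethanolamine methyltransferase, stood at -1.35 in snf2 minimal and -1.19 in swi1 rich. They passed in snf2 minimal without replicate 3 (adjusted p = 0.0353), and blocked in both mutants in minimal medium (adjusted p = 0.0109 and 0.0307).

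Of hexose transporter genes, 5, 4, 3 and 4 of 16, 16, 13 and 14 rose and 6, 7, 5 and 3 fell (5, 5, 3 and 4 higher and 6, 7, 6 and 3 lower adjusted over the list alone). The low-affinity HXT1 (YHR094C) stood at -1.43, -1.57, -0.97 and -1.18 and the high-affinity HXT2 (YMR011W) at 1.03 and 1.33 in minimal medium. Their blocked values in minimal medium passed (adjusted p = 0.00173 and 0.0245). Of tricarboxylic acid cycle and respiratory genes, 7, 9, 7 and 7 of 45, 45, 28 and 43 rose and 6, 5, 5 and 11 fell (8, 9, 7 and 7 higher and 6, 5, 5 and 11 lower adjusted over the list alone). CIT2 stood at 1.93 and 2.62 in rich medium (1.03 and 2.83 on snf2 rich replicates 2 and 3) and COX5B (YIL111W), the hypoxic cytochrome oxidase subunit, at -1.20 and -1.06 in minimal medium. Of gluconeogenesis, glyoxylate and acetate genes, 6, 5, 5 and 7 of 13, 14, 11 and 14 rose and 1, 1, 0 and 1 fell (6, 5, 5 and 7 higher and 1, 1, 0 and 1 lower adjusted over the list alone). MDH2 (YOL126C), cytosolic malate dehydrogenase, stood at 1.38 and 0.74 in minimal medium. Blocked, the list passed in snf2 minimal, swi1 minimal and swi1 rich (adjusted p = 0.0307, 0.0298 and 0.00564). Of serine and glycine genes, 1, 1, 3 and 2 of 10, 10, 9 and 9 rose and 3, 3, 2 and 2 fell (1, 1, 3 and 2 higher and 3, 3, 2 and 2 lower adjusted over the list alone). GCV1 (YDR019C) of glycine cleavage stood at -1.49 and -1.31 in minimal medium and CHA1 (YCL064C), serine deaminase, at -1.44 and -1.36 in rich. Of purine and pyrimidine genes, 3, 3, 2 and 5 of 23, 24, 19 and 23 rose and 9, 10, 6 and 6 fell (5, 3, 2 and 5 higher and 11, 12, 6 and 8 lower adjusted over the list alone). ADE17 (YMR120C) stood at -1.32 and -1.21 in minimal medium and URA2 (YJL130C) at 1.61 and 1.51 in rich. Of iron, copper and zinc uptake genes, 1, 1, 3 and 8 of 22, 25, 19 and 23 rose and 7, 10, 5 and 8 fell (2, 2, 3 and 8 higher and 7, 10, 5 and 8 lower adjusted over the list alone). FET3 (YMR058W), the iron uptake oxidase, stood at -2.00 and -2.43 in minimal medium, and the swi1 minimal test passed without replicate 2 (adjusted p = 0.0287) and blocked (adjusted p = 0.0172).

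Of G2/M genes, 1, 1, 0 and 1 of 12, 12, 8 and 9 rose and 5, 1, 3 and 2 fell (1, 1, 0 and 1 higher and 5, 1, 3 and 2 lower adjusted over the list alone). CLB1 (YGR108W), a mitotic cyclin, stood at -2.62, -2.45 and -2.26 in snf2 minimal, swi1 minimal and swi1 rich. Of flocculins, seripauperins and cold-shock mannoproteins, 5, 3, 3 and 7 of 20, 20, 13 and 20 rose and 0, 0, 4 and 5 fell (5, 2, 3 and 8 higher and 0, 0, 4 and 5 lower adjusted over the list alone). TIR2 (YOR010C) stood at -1.71 and -1.59 in rich medium. Of meiosis and sporulation genes, 6, 6, 7 and 8 of 29, 32, 18 and 30 rose and 0, 1, 0 and 0 fell (5, 6, 7 and 8 higher and 0, 1, 0 and 0 lower adjusted over the list alone). SPO20 (YMR017W) stood at 1.28, 0.86, 1.00 and 1.41. Their test gave adjusted p = 0.0711, 0.0648, 0.111 and 0.0663. It passed without swi1 minimal replicate 3, snf2 rich replicate 2 or swi1 rich replicate 2 (adjusted p = 0.043, 0.0307 and 0.03). Blocked, it passed in all 4 groups (adjusted p = 0.0214, 0.00735, 0.00735 and 0.00234). Of auxotrophic marker genes in snf2 minimal, swi1 minimal and swi1 rich, 2, 1 and 4 of 6, 5 and 6 rose and 2, 1 and 1 fell (2, 1 and 4 higher and 4, 1 and 2 lower adjusted over the list alone). LEU2 stood at 1.62 in snf2 rich and URA3 (YEL021W) at -0.83 in swi1 rich. The marker list passed blocked in swi1 rich (adjusted p = 0.0472). Median, mean and test differed in sign for several of these uncalled lists. Examples were serine and glycine genes (median -0.04, mean 0.44) and flocculins (median 0.24, mean -0.18) in snf2 rich.

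The 2 mutants had closely similar effects within a medium. Across genes, which are not independent replicates, the mean log2 ratios of snf2 and swi1 correlated at r = 0.90 in minimal medium (5123 genes) and 0.86 in rich medium (3397 genes). Between replicate 1 arrays r was 0.71 in minimal and 0.41 in rich medium. Replicate 1 of snf2 correlated with its own replicates 2 and 3 at 0.52 and 0.58 in minimal and 0.23 and 0.28 in rich medium. For swi1 these were 0.47 and 0.48, and 0.47 and 0.42. Except for swi1 in rich medium they were lower than between the mutants. What the replicate 1 arrays of a medium share, such as their platform, may therefore enter that r. In minimal medium 461 genes rose and 612 fell in both, where independent lists would share 92.1 and 126.5, and 0 went opposite ways. In rich medium 467 rose and 604 fell in both (129.0 and 166.9 if independent), and 2 went opposite ways. Whether wild-type RNA was shared between arrays is not given in the sources used here. Simulated arrays with no effects that share it between arrays of 1 replicate number had a covariance of 0.0164 and 0.0175, against 0.270 and 0.317 observed. Their r of about 0.50 was fixed by giving 0.50 of each array's variance to the shared RNA, so only the covariances are compared. Wild-type RNA shared by all arrays of a medium does not enter the spread between arrays, so this simulation sets no limit on it.

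Tested directly, limma called 0 of 5123 genes as different between snf2 and swi1 in minimal medium, with 280 at an unadjusted p under 0.05 where 256 would pass by chance. The 3 genes with the smallest p were TPO2 (YGR138C), a polyamine transporter (0.95, adjusted p = 0.538), CDC39 (YCR093W), a subunit of the Ccr4-Not complex (1.01), and TYE7 (YOR344C), an activator of glycolytic genes (0.95). Without snf2 minimal replicate 3 the count was 18. In rich medium 1 of 3397 genes passed, TSL1, higher in snf2 than in swi1 by 1.76 ± 0.14, adjusted p = 0.00861, with 226 at an unadjusted p under 0.05 where 170 would pass by chance. That count lay between 7 and 66 without 1 array, with 66 without snf2 rich replicate 2 and 7 without swi1 rich replicate 3. Few differing calls do not show that the mutants act alike gene by gene, since a difference had a median standard error of 0.16 in minimal and 0.17 in rich medium.

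**Figure D4:**
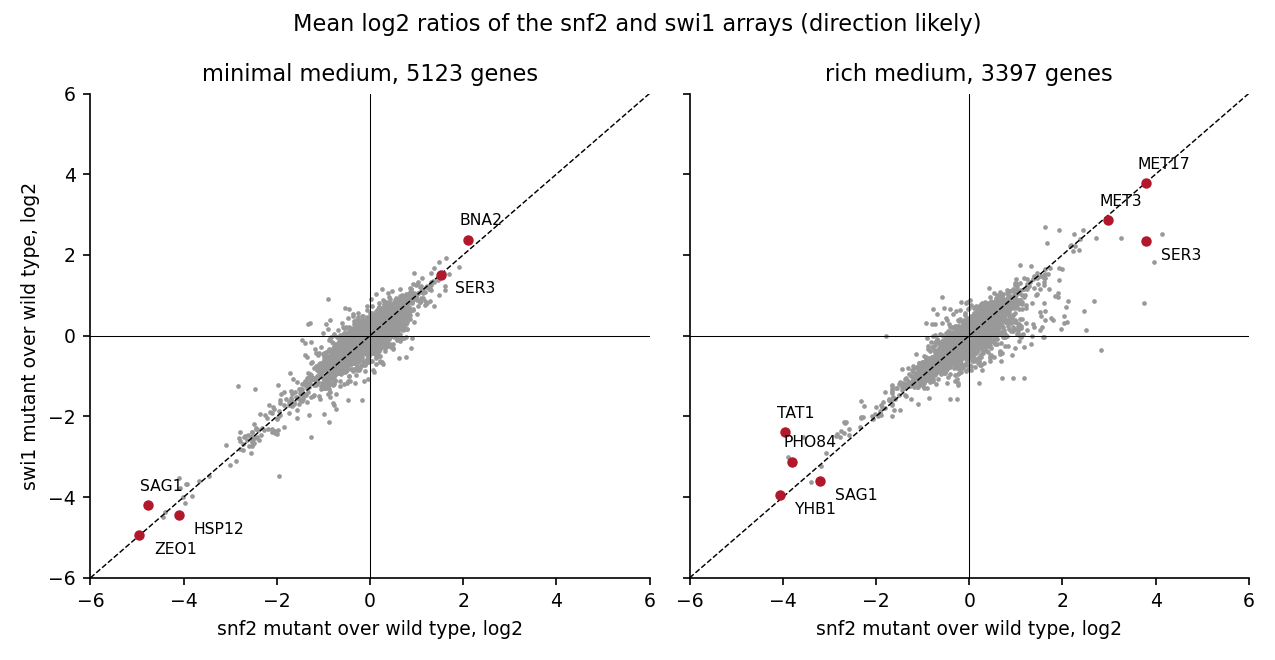
Each point is a gene, with its mean log2 ratio, mutant over wild type, in snf2 on the x axis and in swi1 on the y axis, for minimal medium (5123 genes) and rich medium (3397 genes). The points lie along the diagonal, with r = 0.90 and 0.86 across genes.

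For some genes the effect of a deletion differed between the media. In snf2, YHB1 was higher in minimal than in rich medium by 3.25 ± 0.13, adjusted p = 2.13e-05, ARO9 (YHR137W), an aromatic aminotransferase, by 2.88 ± 0.29, adjusted p = 0.00131, and PHO12 (YHR215W), an acid phosphatase, by 2.88 ± 0.41, adjusted p = 0.00685. PHO12 read 0.86 and -0.58 on snf2 minimal replicates 2 and 3. MET17 differed by -3.10 ± 0.12, adjusted p = 2.13e-05 and ARG1 by -3.28 ± 0.15, adjusted p = 3.44e-05, both lower in minimal medium. In swi1, YHB1 differed by 3.35 ± 0.13, adjusted p = 3.25e-05, ARO9 by 3.19 ± 0.29, adjusted p = 0.00111, PHO84 by 2.71 ± 0.18, adjusted p = 0.000297 and PHO5 by 2.14 ± 0.16, adjusted p = 0.000481. The 4 ASP3 copies, which a probe cannot separate, differed by -4.46 to -4.73.

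limma called 178 of 3559 genes as different between media in snf2 (46 higher and 132 lower in minimal medium) and 306 of 4890 in swi1 (101 and 205). Mean effects in the 2 media correlated across genes at r = 0.65 in snf2 and 0.59 in swi1, and on replicate 1 arrays at 0.26 and 0.48. The same simulation had a covariance of 0.0167 and 0.0170 against 0.222 and 0.181 observed, and its r of about 0.50 was again fixed in advance. It treats wild-type RNA as shared between the media, although each array held RNA from 1 medium. Of called genes, 316 rose and 466 fell in both media in snf2 (100.1 and 132.8 if independent) and 29 went opposite ways, and in swi1 401 rose and 488 fell in both (132.4 and 155.6 if independent) and 51 went opposite ways. The snf2 count was 77 without snf2 minimal replicate 2 and 108 without replicate 3, and the swi1 count was 113 without swi1 minimal replicate 3, 202 without replicate 2 and 165 without swi1 rich replicate 3.

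The list test on the medium difference, chosen after seeing the data and adjusted in its own family, is given in the order snf2, swi1. Of methionine and sulfate genes 12 and 13 of 18 and 20 were lower in minimal medium (16 and 18 adjusted over the list alone). They had adjusted p = 3.28e-38 and 3.48e-29, and adjusted p = 0.186 and 0.186 with an estimated correlation. Of phosphate regulon genes 7 and 6 of 10 and 13 were higher and 0 and 1 lower (8 and 10 and 0 and 1 adjusted over the list alone). These had adjusted p = 4.49e-14 and 6.17e-09, and adjusted p = 0.198 and 0.198 with an estimated correlation. Of genes for arginine, histidine, lysine and branched-chain amino acids 14 and 13 of 26 and 29 were lower and 2 and 3 higher (16 and 17 and 3 and 3 adjusted over the list alone). Amino acid genes had adjusted p = 3.60e-14 and 2.16e-12, and adjusted p = 0.198 and 0.198 with an estimated correlation. Of glycolysis genes 6 and 6 of 18 and 17 were lower and 0 higher (11 and 9 and 0 adjusted over the list alone). That list had adjusted p = 2.36e-07 and 0.000218, and adjusted p = 0.272 and 0.292 with an estimated correlation. Of nitrogen catabolite repressed genes 1 and 8 of 6 and 17 were lower and 0 higher (3 and 12 and 0 and 1 adjusted over the list alone). Nitrogen genes had adjusted p = 0.0859 and 8.17e-33, and adjusted p = 0.311 and 0.292 with an estimated correlation. The former test had 6 and 17 members and the latter 6 in each mutant, which does not show that the mutants differ.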

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

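The tests on dim spots and on hybridisation batch were set before their result was seen, and those on shared wild-type RNA and on dye bias were chosen after. The groups of 2 arrays are too small for a search for arrays that stand apart.

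The difference between snf2 and swi1 in rich medium passed for 1 gene, TSL1, by 1.76. The difference between minimal and rich medium passed for 178 genes in snf2 and 306 in swi1. In snf2 the most positive were TAT1 at 4.84, YHB1 at 3.25, PHO12 at 2.88 and ARO9 at 2.88, and the most negative MEP2, an ammonium permease, at -3.92, ARG1 at -3.28, HIS5 of histidine synthesis at -3.13 and MET17 at -3.10. Of these TAT1 did not pass without snf2 minimal replicate 2 or 3 (adjusted p = 0.085 and 0.088), nor did MEP2 (adjusted p = 0.126 and 0.173) or HIS5 (adjusted p = 0.2 and 0.177). On snf2 rich replicates 2 and 3 TAT1 read -2.48 and -5.43, MEP2 0.62 and 3.55 and HIS5 1.32 and 4.04, and PHO12 read 0.86 and -0.58 in snf2 minimal. In swi1 they were YHB1 at 3.35, ARO9 at 3.19, PHO84 at 2.71 and PHO5 at 2.14, and ASP3-4 at -4.73, ASP3-2 at -4.56, ASP3-3 at -4.48 and ASP3-1 at -4.46.

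By lists, the medium difference at the preset correlation had medians in snf2 of 1.27 for the phosphate regulon, -1.66 for methionine and sulfate genes, -0.64 for arginine, histidine, lysine and branched-chain amino acids, -0.58 for glycolysis, and 0.27 for ribosome biogenesis. Smaller lists had -0.69 for genes with reported Snf/Swi-dependent transcription, -0.54 for phospholipid and inositol genes, -0.41 for serine and glycine genes, -0.34 for mating genes and -0.38 for M/G1 genes. In swi1 the medians were 0.97 for the phosphate regulon, -1.43 for methionine genes, -0.53 for amino acids, -0.49 for glycolysis, -2.53 for nitrogen catabolite repressed genes and 0.29 for ribosome biogenesis. None of these passed with an estimated correlation, a test on 4 residual degrees of freedom and so of little power. It gave adjusted p = 0.198 with an estimated correlation for the reported targets, adjusted p = 0.311 with an estimated correlation for phospholipid genes and adjusted p = 0.339 with an estimated correlation for serine genes. Mating genes had adjusted p = 0.198 with an estimated correlation and M/G1 genes adjusted p = 0.311 with an estimated correlation. Ribosome biogenesis had adjusted p = 0.311 and adjusted p = 0.358 with an estimated correlation in snf2 and swi1.

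The effects of snf2 and swi1 within a medium were alike (r = 0.90 and 0.86 across genes), as 2 deletions in 1 complex could give. Wild-type RNA shared by arrays of 1 replicate number is argued against, since the covariance between snf2 and swi1 arrays of different numbers was 1.00 times that of the same number in minimal medium and 0.995 times in rich medium (95% interval 0.982 to 1.01). Wild-type RNA shared by all arrays of a medium stays open, since neither this ratio nor the simulated covariance (0.0164 and 0.0175 against 0.270 and 0.317 observed), which rests on the spread between arrays, sets a limit on it. A dye bias of single genes that is the same on all arrays is argued against as the whole cause. It would give a snf2 and a swi1 array the same covariance across media as within a medium. Across media the covariance was 0.716 of that within a medium (0.669 to 0.756). A dye bias that differs between media was not tested by this ratio. For the part shared by both media, such as the 500 genes called 1 way in all 4 groups, a dye bias and the deletions cannot be told apart, because no array of a known other dye orientation is among those used.

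The effects of 1 deletion differed between minimal and rich medium, which the design offers as a biological difference. Values of very dim spots are argued against as the whole cause, since 0.803 of the snf2 count and 0.722 of the swi1 count was reached without values at small whole-number ratios, although fewer genes were then tested. A hybridisation batch of the media among replicates 2 and 3 is argued against, since on the separately made replicate 1 arrays 77.8% of called genes in snf2 (119 of 153, 95% exact interval 70.4 to 84.1) and 235 of 283 in swi1 (78.1 to 87.2%) had a medium difference of the same sign. Replicate 1 of each medium was on its own platform, so a batch of that kind is open for those arrays, and wild-type RNA shared by the arrays of a medium was not tested. A response to the medium that depends on Snf/Swi may account for the pattern, as a hypothesis found on these data; wild type against wild type and mutant against mutant of the 2 media, with dyes swapped, would test it.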

How the results depend on the processing

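Settings added after seeing the data were values at small whole-number ratios left out and genes with a single probe. The counts for the 4 groups stayed within 1.5 times of those reported without centring, with scaling, a robust variance model, a replicate block, only the arrays compared and both added settings, and, except for snf2 minimal, on genes measured on all 8 arrays. There it was 1033, with fewer genes tested. With all 12 arrays and platform as a random block the counts were 335, 328, 538 and 408 (snf2 minimal, swi1 minimal, snf2 rich, swi1 rich). For the medium differences in snf2 and swi1 they were 87 and 92. With no block they were 500, 507, 749, 649, 42 and 41. With the block 85, 95, 192 and 161 genes were higher and 250, 233, 346 and 247 lower in the 4 groups, so the balance moved as well. The cause of the lower counts was not tested. Requiring 2-fold left 251, 272, 291, 305, 99 and 147 by construction, and 2-fold on both arrays without a test left 208, 208, 202 and 226. Fitted only to the arrays compared, the medium differences had 98 and 179 genes, with fewer samples. With a replicate block the counts were 1385, 1326, 1438, 1865, 134 and 211, although the numbers did not pair the arrays (r of deviations from -0.03 to 0.02 over 3207 genes).

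The 1 gene that differed between mutants in rich medium became 2 without centring, on genes measured on all 8 arrays, with a robust variance model, without values at small whole-number ratios and with single-probe genes, and 0 with all 12 arrays (either way) and with only the arrays compared; the 0 in minimal medium stayed 0 under these settings. With 1 array left out, where the lone array is assumed to vary like the others, counts ranged from 685 to 1551 for snf2 minimal, 586 to 1526 for swi1 minimal, 1029 to 1197 for snf2 rich, 1054 to 2077 for swi1 rich, 0 to 18 and 7 to 66 for the mutant differences in minimal and rich medium, and 77 to 229 and 113 to 311 for the medium differences in snf2 and swi1. The upper values for snf2 minimal, swi1 minimal, swi1 rich and the snf2 medium difference were without snf2 rich replicate 3, which lacks the most values.

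The share of called genes with the same sign on replicate 1 was 82.5% in swi1 minimal and 71.3% in snf2 rich without centring, and 89.2%, 93.9%, 79.4% and 82.2% in the 4 groups at 2-fold or more. Correlations across genes (mutants in minimal, mutants in rich, media in snf2, media in swi1) were 0.83, 0.77, 0.59 and 0.54 between single arrays of different replicate numbers, and 0.71, 0.41, 0.26 and 0.48 between replicate 1 arrays. That of the media in swi1 was 0.64 on genes measured on all 8 arrays, and with 1 array left out they were 0.84 to 0.88, 0.78 to 0.85, 0.60 to 0.64 and 0.52 to 0.61. List calls numbered 42 of 115 without centring, 43 with scaling, 33 on genes measured on all 8 arrays, 43 with a replicate block, 57 with all 12 arrays and 40 to 49 with 1 array left out, and 0 with an estimated correlation.

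With all 12 arrays and platform as a random block, the heat shock and general stress list pointed down in snf2 minimal (adjusted p = 0.0452), where it pointed up uncalled, and down in snf2 rich (adjusted p = 0.788), where it was called up. With all 12 arrays and no block, RSC8 (1.21), HOF1 (0.79) and CDC5 (0.23), called lower in snf2 rich, were positive. Those 3 calls each needed both snf2 rich arrays. Without replicate 2 and without replicate 3 the values were -0.42 and -0.24 for RSC8, -0.60 and -0.37 for HOF1 and -0.385 and -0.32 for CDC5. The turns to positive rest on the replicate 1 array of snf2 rich. No other named gene or list that was called under either of 2 settings compared reversed. Uncalled lists did turn, such as G2/M genes from down to up in the 4 groups, both on genes measured on all 8 arrays and with an estimated correlation. Of 477 values of named genes, 463 kept their side of the threshold without centring, 465 with scaling and 462 with a replicate block, while 105 of 437 dropped below it with all 12 arrays and no block. With each array left out in turn, 104 of the 477 dropped below it at least once (164 of 994 fits). Signal over background is not given in the sources used here, so how far dim spots limit single values stays unknown.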

Other observations

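Across all 4 groups, 3207 genes could be tested in each, and 194 were called higher and 306 lower in all 4, where independent lists would share 2.64 and 4.37. Of these 16 rose and 57 fell at least 2-fold in every group, a selection made after their values were seen. The 16 included SER3, BNA2, RTS3, EMI2 and MAL31, and also ALD4, a mitochondrial aldehyde dehydrogenase, at 1.30, 1.13, 2.38 and 2.39 in snf2 and swi1 in minimal and in rich medium. Among the losses in all 4 groups, STE3, the a-factor receptor, stood at -2.79, -2.39, -1.66 and -1.71, SST2, which damps pheromone signalling, at -2.79, -2.60, -2.07 and -2.08, and FUS3, a mating kinase, at -1.51, -1.60, -1.58 and -1.58. MATALPHA1, the activator of alpha-specific genes, stood at -1.69, -1.58, -1.48 and -1.18, but its silent copy HMLALPHA1 shares its sequence (-1.80, -1.58, -1.66 and -1.36), so a probe cannot separate them. SED1, a cell wall glycoprotein, stood at -2.78, -2.82, -2.83 and -2.43, and WSC4, a cell wall sensor, at -2.88, -3.10, -1.66 and -1.32. Of the 57, 17 are open reading frames of Ty retrotransposons, an identity that is background and not in the annotation used, with medians of -2.39, -2.32, -1.92 and -1.78; they are near-identical copies and not separate measurements.

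Genes called opposite ways in the 2 media, also chosen after their values were seen, were mostly lower in minimal and higher in rich medium, 21 of 29 in snf2 and 44 of 51 in swi1, and the medium difference itself passed for 28 and 51 of them. In snf2 they included ARG1 (-1.39 and 1.90), DIP5, a dicarboxylic amino acid permease (-1.93 and 1.06), LEU1 of leucine synthesis (-0.42 and 1.55) and GLN1, glutamine synthetase (-0.49 and 1.32). In swi1 they included GAP1 (-2.04 and 1.93), DAL7 of allantoin use (-2.69 and 0.36), the proline permease PUT4 (-1.65 and 0.88), ARG3 (-1.09 and 0.88) and ARG7 (-0.30 and 1.69). The reverse was seen for CYC1, cytochrome c, in snf2 (0.36 and -1.30) and in swi1 (0.35 and -1.17), and for CYB5, cytochrome b5, in snf2 (0.42 and -1.08) and in swi1 (0.55 and -0.67).

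Effects went with position on the chromosome, with no biological explanation tested and in tests thought of after other results were known and set before their own result was seen, except the last, chosen after. Adjacent genes correlated in their mean log2 ratio at r = 0.172 over 1930 pairs (permuted gene orders gave -0.06 to 0.07). Neighbouring probe numbers are argued against, since pairs with probes over 20 numbers apart gave 0.185. Probe numbers were not mapped to places on the slide, so a spatial or printing cause stays open. Named, non-overlapping neighbours whose names differ in their letters gave 0.0755 over 1676 pairs (permuted -0.08 to 0.08, 1 of 1000 at least as high). This leaves out overlapping reading frames and many copies, but also unnamed genes and neighbours that share letters without being copies. Cross-hybridising copies, overlapping reading frames and an effect of chromosomal neighbourhood therefore all stay open. Genes near chromosome ends were the 8 outermost at each end among genes tested in all 4 groups, with no limit on distance. COS and Y' genes were left out of them, which left 243. Under the direction used, 34.0% of these were called higher on average over the 4 groups, against 15.4% of 2940 other genes. The difference was 18.5 points (random sets -5.85 to 5.96). Fewer end genes than other genes were called lower, 14.92% against 19.97%. With the opposite reading the higher and lower shares change places. Examples of end genes called higher were DLD3, a lactate dehydrogenase, at 0.98, 1.26, 2.27 and 2.22, and UBP11, a ubiquitin protease, at 1.07, 0.83, 0.75 and 0.66. Repeated families and the position itself cannot be told apart, since 110 named end genes that share no letters with each other differed by 11.5 points (random sets -7.59 to 8.23) but hold genes with copies elsewhere such as THI13, and the 36 whose letters no other annotated gene has differed by 9.96 points (36 of 1000 random sets at least as high).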
